A study of Mus musculus with 9 samples.

How the data were processed

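Plaques of 3 genotypes were each divided into an unsorted library and tdTomato+ and GFP+ sorts of the remaining cells, giving 9 single-cell libraries in 9 groups of 1, mapped from the sample titles. Per the labels' protocols, plaques were digested for 1 hour in Liberase with actinomycin D, which blocks new transcription, 2000 cells were aimed for per library, and the 10x Genomics single cell 3' v2 kit was used. The deposited files are filtered gene by barcode matrices of UMI counts, whole numbers with no normalisation, over 31053 genes. Cell Ranger 2.1.1 and mm10 are named per the submitters' processing notes, while software version 3.0.2 stands in the matrices per the file headers. The counting settings and the annotation are not given in the sources used here. A 3' kit counts UMIs near the polyadenylated end, so a deletion upstream of the tag can leave a gene's UMIs in place, and reads shared by near-identical genes can be dropped or split. Actinomycin D and the digestion bear on immediate early genes. Positions of genes come from the GENCODE annotation of mm10.

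Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left 5069 cells. No barcode of the wild type and knockout tdTomato+ libraries was kept. Their comparisons, and the test between the sorts, were planned on mesenchymal cells and were run on sums over all barcodes of a library instead, a choice made after the data had been seen. Total UMIs per library ran from 1516281 to 32611390. A count of 0 was read as allowing up to 3 counts.

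Kept cells of all libraries were scaled to 10000 UMIs, log-transformed and clustered together with scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2 in Python 3.11.15, with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. The 2000 most variable genes seen in at least 10 cells, 30 principal components, 15 neighbours, resolution 1 and no batch integration gave 27 clusters. Sex genes, haemoglobins, mitochondrial genes and Ccl2 were left out of the variable genes, a choice made after the data had been seen. Clusters were named from 18 marker sets, with at least 3 markers each detected in 25% of the cells. A name was withheld where the 10 top genes held more markers of another class than of its own, if that class also qualified by score and detected markers. Between macrophage-like, monocyte-like and dendritic cell-like sets the name passed to the other class instead. A name was also withheld where cell cycle genes led the 10 top genes, or where depth was low and no marker was among them. These thresholds, set after the data had been seen, left 5 clusters unnamed. A cluster that scored best for an SMC-like, modulated SMC-like, chondrocyte-like or fibroblast-like set but had none of its markers among the 10 top genes was named mesenchymal (6 clusters), and these were joined with the clusters of the 4 names as the mesenchymal class. Scrublet was run on libraries with at least 200 kept cells and marked 23 cells in all, or 0.213% to 1.1% per library. The total was under the 0.5% taken as the least for a working run, so Scrublet was judged not to have worked. A low share alone does not show that it failed. No doublets were removed in the main setting, and doublets may remain in the data.

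UMIs were summed over the cells of a class and given as CPM of that sum. Counts have exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios of 2 counts the exact conditional binomial interval, all at 95%. These intervals cover counting error only. For tests in the closing section, cells were drawn again 1000 times within each library where the text says so. With 1 library per genotype no p-value was computed for genotypes. Genes with at least 30 UMIs over both libraries were compared. The naming rule, fixed before the data were examined, takes among those at least 2-fold apart the 10 per direction whose interval lies farthest from a ratio of 1 at its nearer end. It leaves out mitochondrial, ribosomal protein, haemoglobin, Y-linked and predicted genes and Xist, gives the heterozygous value beside, and also allows Ccl2 and members of the fixed lists. For the sorts it takes the 12 genes per direction with the largest fold change among those called, at a mean of at least 50 CPM and with 1 direction in all 3 genotypes. Of each of 28 gene lists fixed before the data were examined, the median log2 ratio was set against 10000 random lists of the same size, matched on mean CPM in 10 bins, as a description of these libraries. Shares of cells with a UMI were repeated with every cell thinned to 1500 UMIs.

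The sorts were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, genotype as a block, since both sorts of a genotype come from 1 digest per the labels, Benjamini-Hochberg adjustment, threshold 0.05) and with camera of limma 3.58.1 at a preset correlation of 0.01 and at an estimated one. The labels do not say how many animals gave a library. With genotype as a block, these p-values measure the spread of the sort effect between the genotypes. A sort effect that depends on genotype therefore counts as error. DESeq2 1.42.0 was an alternative. Further alternatives were other limits on detected genes (200, 1000), mitochondrial share (5%, 20%) and UMIs per gene (10, 100), resolutions of 0.5 and 2, TMM scaling, thinning, all kept cells, and fits with no block, no filter, all libraries or without 1 genotype pair. Figures were drawn with matplotlib 3.10.9.

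The steps were tested on simulated counts. For GFP+ mesenchymal cells, knockout against wild type, 95.9% of the ratio intervals over 11868 genes held the true ratio. Of 186 genes changed 4-fold 99.5% passed the 2-fold rule, as did 143 unchanged genes. These counts were drawn with Poisson noise alone, which the intervals assume. They check the calculation and do not give the error of the real comparison, where cells and animals differ more. For the sorts, counts were simulated at the estimated dispersion of 0.0757, over 11191 genes. The test recovered 18 of 96 genes changed 2-fold and 95 of 95 changed 8-fold, with 8 of 121 calls false. These shares hold for counts simulated at that dispersion. They do not give the recovery or the false calls of the real test. In the real test the wild type and knockout tdTomato+ libraries held no usable cells.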

Results

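Single-cell 3' RNA libraries were collected from advanced plaques of the mouse brachiocephalic artery, a branch of the aortic arch. The mice carried Myh11-DreERT2, a Dre recombinase that tamoxifen switches on in smooth muscle cells (SMCs), together with Lgals3-Cre, a Rosa reporter and floxed alleles of MCP1, the protein encoded by Ccl2. In this system tdTomato marks the SMC lineage, and GFP marks those of its cells that went on to switch on Lgals3, the gene of galectin 3. Tamoxifen was injected at 6 to 8 weeks of age and the Western diet lasted 18 weeks. Animals with 0, 1 or 2 floxed alleles (wild type, heterozygous and homozygous knockout) each gave an unsorted, a tdTomato+ and a GFP+ library, which makes 9 groups of 1 library. No difference between genotypes therefore has a replicate check. The question was what loss of Ccl2 in Lgals3-transitioned SMCs does to these cells and to the rest of the plaque.

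Unsorted wild type, heterozygous and knockout plaque gave 20781683, 32611390 and 30379311 UMIs over 1644, 3988 and 2679 barcodes, and the GFP+ libraries gave 4953053, 1516281 and 18726963 UMIs over 189, 57 and 786 barcodes. The heterozygous tdTomato+ library held 22664524 UMIs over 1346 barcodes. In the wild type and knockout tdTomato+ libraries 3882762 and 1829511 UMIs were spread over 77827 and 77619 barcodes, at a median of 49 and 23 UMIs each and at most 2828 and 1044. Gm42418 and AY036118, transcripts that overlap ribosomal RNA repeats, took 22.8% and 16.8% of the UMIs there, against 1.64% to 2.22% in the other libraries, and mitochondrial genes 1.02% and 1.54% against 6.56% to 8.95%. No barcode of these 2 libraries passed the cell filter, and they entered comparisons only as sums over the whole library. The filter kept 937, 1244 and 1478 cells of the unsorted libraries, 103, 29 and 554 of the GFP+ libraries and 724 of the heterozygous tdTomato+ library. Median depths per kept cell ran from 15385 UMIs (unsorted knockout) to 44749 (heterozygous GFP+). Xist, the noncoding RNA of the inactive X chromosome, was at 864 to 989 CPM (UMIs of a gene scaled to a common total per library or cell group) in the heterozygous libraries and at no more than 23.8 CPM in the others, so heterozygous libraries differed from both other genotypes in a sex-linked transcript as well.

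Ccl2, the monocyte-attracting chemokine targeted here, lies on chromosome 11 from 82035571 to 82037453 (mm10, plus strand), with Ccl7, Ccl11, Ccl12 and Ccl8 following it on the same strand. Mesenchymal cells join SMC-like, modulated SMC-like, chondrocyte-like and fibroblast-like clusters with 6 clusters named only mesenchymal, since none of their 10 top genes was a marker of the name that scored best. These 6 held 308 of 573 wild type, 471 of 760 heterozygous and 392 of 892 knockout mesenchymal cells of unsorted plaque. Mesenchymal cells of the knockout GFP+ library held 1 Ccl2 UMI, in 1 of 535 cells, or 0.0632 CPM (0.0016 to 0.352). Those of the wild type GFP+ library held 132 UMIs in 11 of 92 cells, or 36.9 CPM (30.9 to 43.7), which is a 584-fold difference (103 to 23226). Over all kept cells, which add 10 unnamed wild type cells with 120 Ccl2 UMIs, it was 341-fold. These intervals, like all others below, are exact 95% intervals that cover counting error only. Ccl2 in the GFP+ sort thus differed between wild type and knockout as their labels name it, although they do not say which exons are floxed, and a 3' tag outside the deleted part would not report the deletion. The heterozygous GFP+ library did not lie between these 2: it was at 321 CPM (292 to 353), 8.71-fold above wild type (7.16 to 10.7), with 83.0% of its 441 UMIs in 1 of 27 cells. In unsorted mesenchymal cells Ccl2 was at 109 CPM in wild type (104 to 115), 45.3 in heterozygous (42.2 to 48.5) and 13.8 in knockout plaque (12 to 15.7), 2.41-fold and 7.93-fold below wild type (2.21 to 2.63 and 6.89 to 9.17). One knockout cell held 33.8% of the 228 UMIs behind the last value, and with other cell filters its ratio to wild type went from 0.126 to as much as 0.230, at 13.7 to 40.4 CPM. In wild type 991 of the 1390 UMIs lay in the cluster led by Grem1 and Mmp3. It held 79 of 573 wild type and 58 of 892 knockout mesenchymal cells, with Ccl2 at 527 and 69.0 CPM. The folds were not compared at equal mix of clusters. A UMI of Ccl2 was seen in 41 of 892 knockout mesenchymal cells (4.6%), against 125 of 760 heterozygous (16.4%) and 109 of 573 wild type cells (19.0%). With every cell thinned to 1500 UMIs these shares were 1.35%, 4.10% and 6.81%, and those of GFP+ mesenchymal cells were 0% and 3.30% in knockout and wild type. The median depths were 16642, 21717 and 20661 UMIs in unsorted and 27079 and 37244 UMIs in GFP+ cells. Among T cell-like cells, which should lack the gene, Ccl2 was seen in 0 of 32, 0 of 30 and 0 of 14 cells of wild type, heterozygous and knockout plaque at median depths of 4127, 4502 and 3162 UMIs, which allows shares of up to 9.38%, 10% and 21.4%.

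Macrophage-like and monocyte-like cells still held Ccl2 in knockout plaque, at lower levels than in wild type. The macrophage-like class was at 363 CPM in wild type (341 to 387), 228 in heterozygous (214 to 241) and 243 in knockout plaque (230 to 257), the last 1.49-fold below wild type (1.37 to 1.63). Monocyte-like cells, the class with the highest level, were at 2344, 1316 and 839.5 CPM, 2.79-fold lower in knockout than in wild type (2.53 to 3.08). This class is 1 cluster that scored best for the macrophage-like set and was led by Il1b and Cxcl2, members of the inflammatory macrophage list. Its name came from 1 monocyte marker, Chil3, among its 10 top genes, so the name is uncertain. Endothelial-like cells held 81, 51 and 0 UMIs, with 67.9% and 78.4% of the first 2 values in 1 cell each. Ccl7, which encodes a related monocyte chemokine 8259 bases downstream of Ccl2, went the other way in the targeted cells. It was at 101 CPM (96.3 to 106) in knockout and 22.6 CPM (18.0 to 28.1) in wild type GFP+ mesenchymal cells. The ratio was 4.47 (3.57 to 5.66), and over all kept cells it was 2.90 (2.44 to 3.47). A Ccl7 UMI was seen in 106 of 535 knockout cells (19.8%) and 9 of 92 wild type cells, or in 5.46% and 1.10% after thinning. Ccl7 was also higher than in wild type in heterozygous GFP+ mesenchymal cells, at 230 CPM with 80.1% of the UMIs in 1 cell, and in the knockout tdTomato+ library, at a ratio of 1.91 (1.498 to 2.43). Unsorted mesenchymal cells were at 34.6, 42.2 and 72.7 CPM of Ccl7 in wild type, heterozygous and knockout plaque, while macrophage-like cells were at 132, 87.6 and 84.0 CPM.

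**Figure D1:**
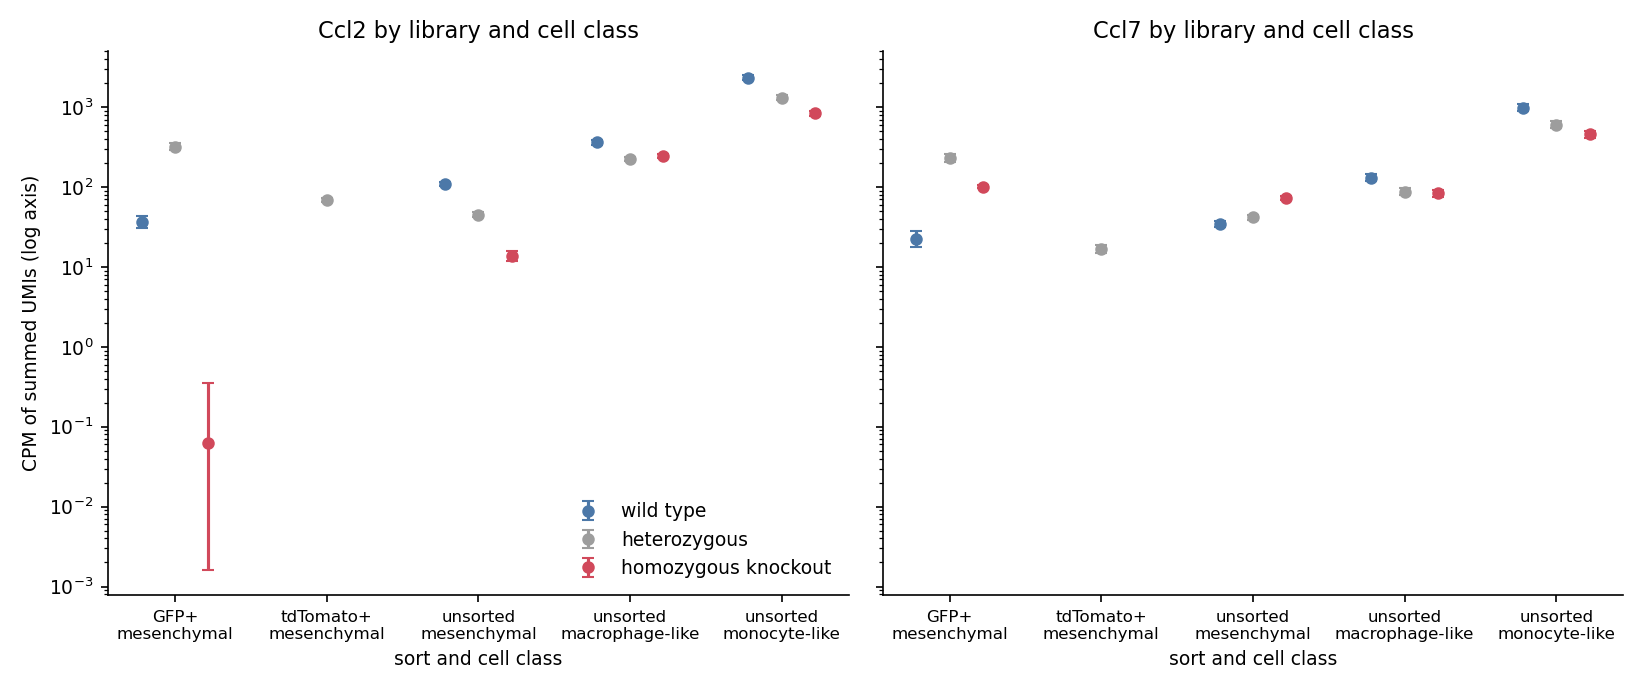
Ccl2 and Ccl7 in mesenchymal, macrophage-like and monocyte-like cells, in CPM on a log axis, with exact 95% Poisson intervals for counting error. Ccl2 is at 0.0632 CPM in knockout GFP+ mesenchymal cells and Ccl7 is higher there (101 CPM) than in wild type GFP+ mesenchymal cells (22.6 CPM).

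The unsorted libraries were then compared for their cell classes, to see whether the plaque held different cells after the deletion. Mesenchymal cells made up 61.2% of wild type (57.9% to 64.3%), 61.1% of heterozygous (58.3% to 63.8%) and 60.4% of knockout plaque cells (57.8% to 62.9%). Macrophage-like cells made up 17.1% (14.7% to 19.6%), 21.2% (19.0% to 23.6%) and 20.8% (18.8% to 23.0%), and monocyte-like cells 3.84%, 3.30% and 4.40%. The intervals of both myeloid classes overlapped between wild type and knockout. These shares depend on the cell filter: with at most 5% mitochondrial UMIs macrophage-like cells made up 44.9%, 35.1% and 46.2%. T cell-like cells were at 3.42% (2.35% to 4.79%), 2.41% (1.63% to 3.42%) and 0.947% (0.519% to 1.58%), B cell-like cells at 1.92% (1.14% to 3.02%), 0.482% (0.177% to 1.05%) and 0.271% (0.0738% to 0.691%), and neutrophil-like cells at 3.74% (2.62% to 5.16%), 0.402% (0.131% to 0.935%) and 1.15% (0.671% to 1.84%). Among the 10 top genes of the T cell-like cluster were Hbb-bs, Hba-a1, Hbb-bt and Hba-a2, beside 2 T cell markers. A cluster that scored T cell-like but stayed unnamed for its cell cycle genes held 2, 19 and 1 further cells. Dendritic cell-like cells were at 1.71%, 2.01% and 2.57% and endothelial-like cells at 2.88%, 3.46% and 1.76%. Haemoglobin genes took 0.552%, 6.87% and 2.64% of all UMIs in the same libraries. Clusters whose name was withheld, by thresholds set after the data had been seen, held 4.27%, 5.63% and 7.71% of the cells. Among them, a cluster scored best for the chondrocyte-like set but had 4 haemoglobin genes among its 10 top genes. That cluster held 1, 4 and 59 cells of wild type, heterozygous and knockout plaque, which are not counted as mesenchymal. In the sorted libraries 89.3% of wild type, 93.1% of heterozygous and 96.6% of knockout GFP+ cells and 88.4% of heterozygous tdTomato+ cells were mesenchymal, shares that the sort sets, with 9.71%, 6.90%, 2.89% and 11.6% unnamed. Macrophage-like cells were 1 of 103 in the wild type and 3 of 554 in the knockout GFP+ library.

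**Figure D2:**
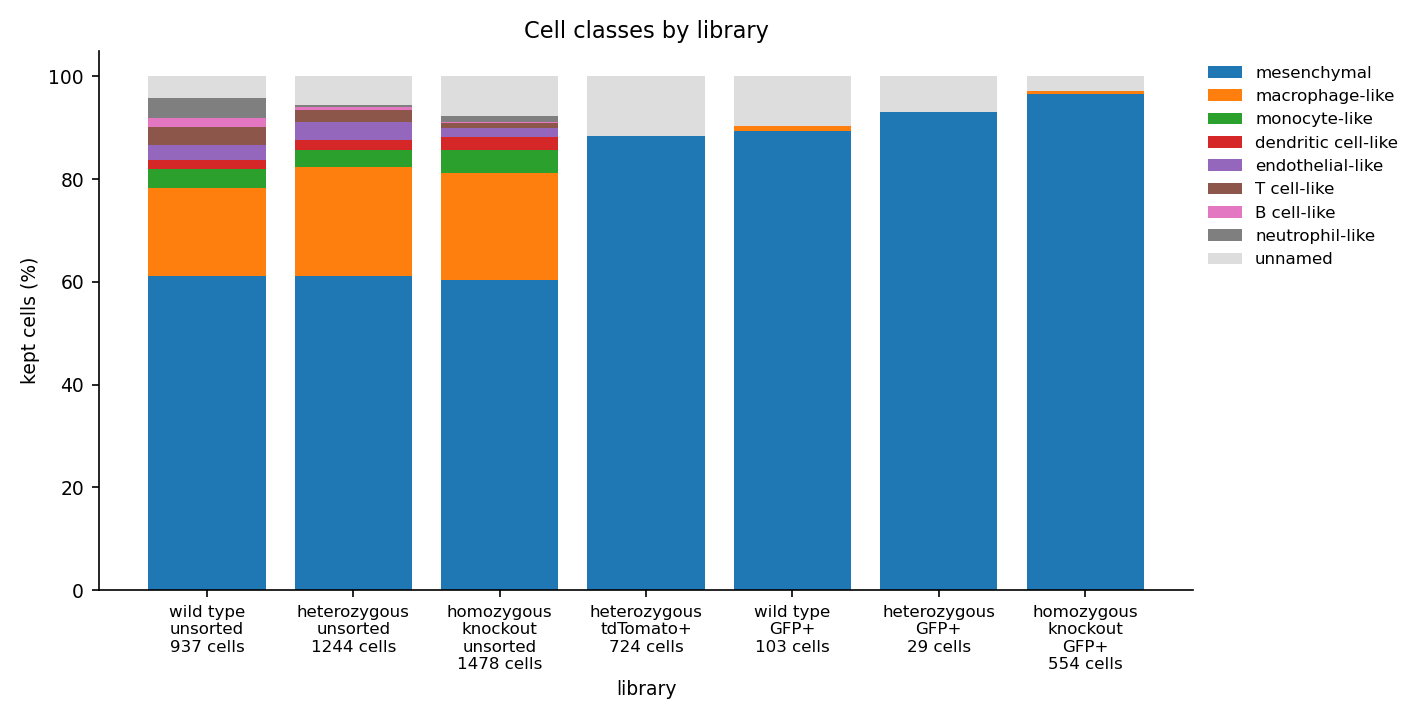
Percent of kept cells in each class, stacked to 100%, in the 7 libraries with usable cells; the number of kept cells stands under each bar. Mesenchymal cells sit at 60.4% to 61.2% in the unsorted libraries and at 88.4% to 96.6% in the sorted ones.

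Knockout GFP+ mesenchymal cells had higher levels of genes of mineralising cartilage and bone than wild type ones. Col10a1, the collagen of hypertrophic cartilage, was 10.9-fold higher (8.59 to 13.9) and was detected in 83 of 535 knockout and 6 of 92 wild type cells, with 58.3 CPM in the heterozygous sort. The osteocalcin genes Bglap and Bglap2, near-identical copies whose counts cannot be fully told apart, were 12.2-fold (6.75 to 24.5) and 20.4-fold higher (11.1 to 42.7), with 45.8% and 63.2% of the knockout UMIs in 1 cell and 0.729 and 0 CPM in the heterozygous sort. Panx3, a pannexin channel of osteoblasts and hypertrophic chondrocytes, was at least 14.6-fold higher, with 0 wild type and heterozygous UMIs against 194 in knockout. Of the fixed chondro-osteogenic list, 4 of 18 measured genes were at least 2-fold higher and 0 at least 2-fold lower. Ibsp, bone sialoprotein, was at 5493 CPM in wild type and 11999 in knockout cells, Hapln1, which links proteoglycans to hyaluronan, at 234 and 613, and Cytl1, a secreted cartilage protein, at 1533 and 3251, whereas Col2a1, the main cartilage collagen, was at 14069 and 9994. The list's median log2 ratio was 0.32, at percentile 100 of 10000 random lists of the same size and expression. At equal mix of clusters drawn without the list's genes it was -0.12 (percentile 0.5), with wild type clusters of as few as 1 cell. In the knockout sort most mesenchymal cells lay in clusters led by Cytl1 and Wif1, by Nos2 and Il6 and by Alpl and Col10a1, and in wild type in clusters led by Tnfrsf11b and Nt5e, by Mmp13 and Saa3, by Cytl1 and Wif1 and by Grem1 and Mmp3. The cartilage clusters and the list rest on the same genes.

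Among other genes higher in knockout GFP+ mesenchymal cells, Irx5, a homeobox transcription factor, was at 2.24, 6.56 and 18.8 CPM in wild type, heterozygous and knockout cells, a ratio of 8.42 (4.22 to 19.7), and Il17d, a cytokine of the interleukin 17 family, at 4.47, 18.9 and 30.3 CPM, a ratio of 6.77 (4.13 to 11.9). They were seen in 137 and 162 knockout cells. Otor, a secreted cartilage protein, was 19.1-fold higher (8.70 to 52.2), Timp4, a metalloprotease inhibitor, at least 12.3-fold, Saa1, an acute-phase protein with close paralogs, 16.8-fold (5.68 to 82.1) and Padi2, a peptidylarginine deiminase, 29.4-fold (5.19 to 1170), with 160, 0.729, 6.56 and 12.4 CPM in the heterozygous sort. Lower in knockout after Ccl2 were Ptn, the growth factor pleiotrophin (6.37-fold, 5.33 to 7.63), Il33, an alarmin cytokine (7.87-fold, 5.30 to 11.8), and Sfrp1, a Wnt antagonist (6.80-fold, 4.74 to 9.84). Their heterozygous levels were 174, 4.37 and 21.9 CPM, and 54.4% of the wild type Ptn and 56.2% of the wild type Il33 UMIs lay in 1 cell. Actg2, an SMC actin (8.00-fold), Mfap4, an elastic fibre protein (48.6-fold), and Tnni2, a troponin (75.2-fold), were lower with 80.0%, 71.9% and 100% of their wild type UMIs in 1 cell. R3hdml (13.3-fold), Wfdc2 (11.1-fold) and Pcdhga1 (10.2-fold, which shares its 3' exons with other protocadherins) were lower at 48, 25 and 23 wild type UMIs, with 47.9%, 52.0% and 21.7% of them in 1 cell.

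The inflammatory lists did not move together in GFP+ mesenchymal cells. Among 12 measured CC and CXC chemokines 2 were at least 2-fold higher and 4 lower, with a median log2 ratio of -0.44 (percentile 0). Ccl9 was 5.0-fold and Cxcl5, a neutrophil chemokine, 3.06-fold lower. The cytokine and NF-kB target list had a median of 0.37 (percentile 99.98), with Il6 at a ratio of 2.85 and Nfkbiz, an inducible NF-kB cofactor, at 2.03. Immediate early and dissociation response genes, which tissue digestion can induce, had a median of 0.66 (percentile 100), with Egr1 at 1.77 and Fos at 1.92. The cluster led by Nos2 and Il6 held 103 of 535 knockout and 4 of 92 wild type cells, and these 2 lists were not compared at equal mix of clusters. Complement genes had a median of -0.74 (percentile 0 over 7 genes), with C3 1.71-fold and C4b 1.84-fold lower, and 7 of 18 interferon response genes were at least 2-fold lower at a median of -0.38. The contractile list had a median of -0.26 (percentile 0.15), but 0.09 without the cell with the most UMIs of each gene, a setting that takes 1 of 92 wild type and 1 of 535 knockout cells. Matrix genes were at -0.23, SMC modulation genes at 0.02, hypoxia genes at -0.24 and oxidative phosphorylation genes at 0.02. By the size rule alone, which is not a test, 395 genes were at least 2-fold higher and 291 lower among the 11897 with 30 or more UMIs.

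**Figure D3:**
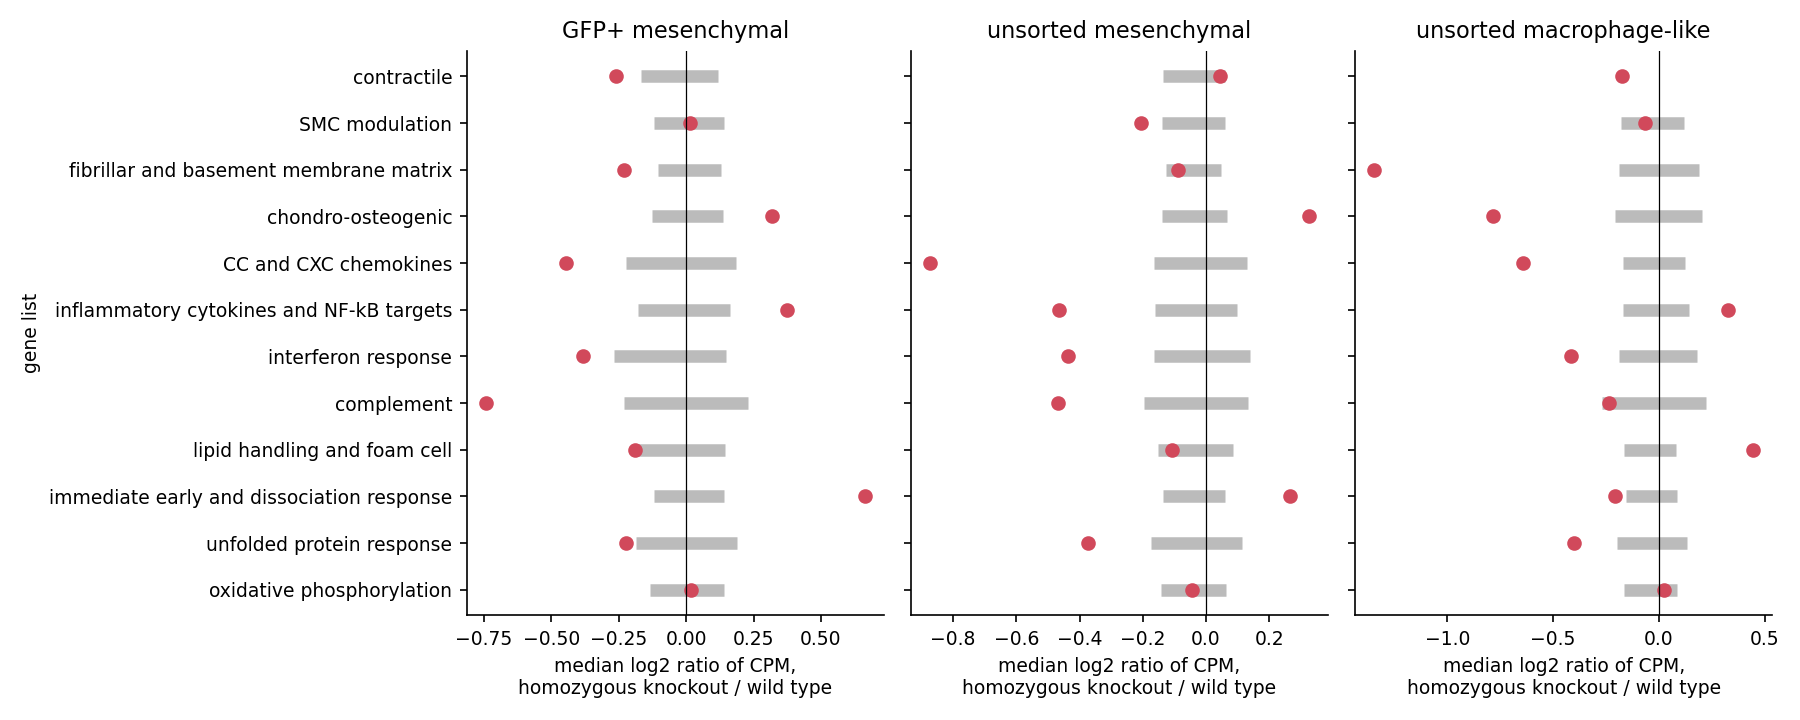
Median log2 ratio of CPM, homozygous knockout over wild type, of 12 gene lists (red) in 3 cell groups with their own axis ranges, over the middle 95% of 10000 random lists of the same size and expression (grey; not drawn for the contractile list in macrophage-like cells, with 3 genes measured). The chondro-osteogenic list lies right of the grey bar in both mesenchymal panels (0.32 in each) and left of it in macrophage-like cells (-0.78, where 47.3% to 53.8% of the wild type UMIs of Ibsp, Sox9, Hapln1 and Fmod lie in 1 cell each).

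In unsorted mesenchymal cells, which hold SMC-derived and other cells, knockout plaque had less Ccl2 and less of several other inflammatory genes. Il6, a pleiotropic cytokine, was 18.3-fold lower (14.3 to 23.9) with 70.8% of the wild type UMIs in 1 cell, and Saa2, an acute-phase protein, was 12.6-fold lower (10.4 to 15.5) with 49.3% in 1 cell; heterozygous levels were 4.73 and 0.844 CPM. Chemokines as a group were lower: 8 of 17 were at least 2-fold lower and 1 higher, at a median log2 ratio of -0.87 (percentile 0; -0.474 with at least 100 UMIs and -0.633 without each gene's top cell), with Cxcl5 5.37-fold, Ccl9 3.57-fold and Ccl5, a T cell attractant, 8.26-fold lower (88.5% of its wild type UMIs in 1 cell). In the cytokine and NF-kB list 5 of 15 genes were at least 2-fold lower and 0 higher, at a median of -0.47 (percentile 0; -0.248 with at least 100 UMIs), with Saa3 2.67-fold, Vcam1, an adhesion molecule, 1.66-fold and Lcn2, lipocalin 2, 1.64-fold lower. Interferon response genes were at -0.44, complement genes at -0.47, unfolded protein response genes at -0.37 and SMC modulation genes at -0.20. Beside these, the macrophage marker list was at -1.29, inflammatory macrophage genes at -1.04 and MHC class II genes at -1.15 in the same mesenchymal cells, and erythroid genes at 1.94.

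Other genes lower in unsorted knockout mesenchymal cells were Stfa3, a cystatin with close paralogs (17.4-fold, 11.45 to 27.5), Wfdc17 (13.4-fold), Fcrls (17.9-fold) and Col22a1, a collagen of tissue junctions (15.9-fold), at 19.4, 1.58, 1.24 and 5.23 CPM in the heterozygous library, and 72.7% of the 55 wild type Fcrls UMIs lay in 1 cell. Fcrls and Wfdc17 were among the 10 top genes of macrophage-like clusters, and the macrophage marker list was at -1.29 in these mesenchymal cells. Wfdc17 was at 1096 CPM in wild type macrophage-like cells and 5.65 CPM in wild type mesenchymal cells. Whether UMIs of these 2 genes came from mesenchymal cells was not tested. Myct1 (54.7-fold, 9.29 to 2210) and Rab37 (40.3-fold, 6.72 to 1644) rested on 1 knockout UMI each, and Cyp26a1, a retinoic acid hydroxylase, was at least 19.1-fold lower at 0 against 44 UMIs, 54.5% of them in 1 cell. Higher in knockout was Zbtb16, a zinc finger transcription factor, at 4.55, 3.99 and 42.8 CPM in wild type, heterozygous and knockout cells, a ratio of 9.41 (7.19 to 12.5) carried by 319 of 892 knockout and 53 of 573 wild type cells. Otor was 17.9-fold higher (10.9 to 31.6), in 39 and 6 cells, with 2.19 CPM in heterozygous cells. Several others came from few cells. Muc16 (at least 22.3-fold), Msln (at least 8.71-fold) and Upk3b (28.4-fold), genes of mesothelium, were seen in 2, 2 and 5 knockout cells, Gpm6a (at least 12.6-fold) in 3, Epyc, a cartilage proteoglycan (18.3-fold), in 5, Mucl1 (at least 18.9-fold) in 1, Chrdl2, a BMP antagonist (21.0-fold), in 11 and Rgs17 (at least 9.22-fold) in 21. The chondro-osteogenic list was at 0.32 (percentile 100; 2 of 18 genes at least 2-fold higher, 0 lower), and at 0.068 (percentile 89.2) at equal mix of clusters drawn without its genes, with Col2a1 at a ratio of 2.55, Cytl1 at 2.20 and Acan, the large cartilage proteoglycan, at 1.89. Immediate early genes were at 0.26, TGF-beta and YAP targets at 0.13 and contractile genes at 0.04. The largest clusters of this class were those led by Cytl1 and Wif1 (181 cells) and by Alpl and Col10a1 (132) in knockout, and by Grem1 and Mmp3 (79) and by Mmp13 and Saa3 (71) in wild type. The size rule took 235 genes as higher and 204 as lower among 12601.

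Macrophage-like cells of knockout plaque had more transcripts of lipid handling. Fabp5 and Fabp4, fatty acid binding proteins, were 2.22-fold (2.16 to 2.28) and 5.16-fold higher (4.52 to 5.91), with 2475 against 5502 CPM and 89.4 against 461 CPM. Heterozygous macrophage-like cells had 3884 and 224 CPM. The lipid handling and foam cell list was at a median log2 ratio of 0.45 (percentile 100), with 3 of 18 genes at least 2-fold higher and 0 lower, and Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, at a ratio of 1.95. The cluster led by Gpnmb and Fabp5 held 43 of 160 wild type and 150 of 308 knockout cells, and the list was not compared at equal mix. Erythroid genes were at 2.34 in the same cells, with 4 of 4 at least 2-fold higher. Cd5l, an apoptosis inhibitor of macrophages, was 3.91-fold higher (3.58 to 4.29) and the resident-like macrophage list was at 0.46 (percentile 99.96). Vcam1 (6.40-fold), Hpse, the heparan sulfate cleaving heparanase (5.09-fold), and Npl, a sialic acid lyase (4.09-fold), were higher too. So were Thbs1, thrombospondin 1 (3.06-fold), F7, coagulation factor VII (3.06-fold), and Tns1, a focal adhesion protein (2.91-fold). In this order the 6 genes had 9.33, 11.2, 17.0, 22.5, 66.3 and 29.8 CPM in heterozygous cells. Bex1 was 59.3-fold higher (10.4 to 2365) against 1 wild type UMI.

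Lower in knockout macrophage-like cells was Wfdc17, a secreted protein of activated macrophages (4.23-fold, 3.96 to 4.52; 1096, 536 and 259 CPM in wild type, heterozygous and knockout). Chemokines were at a median log2 ratio of -0.64 (percentile 0; 0 of 14 at least 2-fold higher, 2 lower), with Ccl9 2.48-fold, Cxcl10, an interferon-induced chemokine, 2.07-fold, Ccl3 1.85-fold and Ccl4 1.64-fold lower. The interferon response list was at -0.41, the unfolded protein response at -0.40, inflammatory macrophage genes at -0.22 and immediate early genes at -0.21, while cytokine and NF-kB targets were at 0.33 (percentile 100), the macrophage marker list at 0.11 and MHC class II genes at 0.02. Genes of mesenchymal cells were lower as well: Ibsp (14.8-fold), Col1a1, the main fibrillar collagen (6.45-fold), Dcn, decorin (3.67-fold), Sox9, the cartilage transcription factor (19.8-fold), Hapln1 (27.1-fold), Fmod (6.23-fold), Col6a1 (5.19-fold) and Pcolce2 (13.4-fold). Between 44.6% and 53.8% of the wild type UMIs of each of these 8 genes lay in 1 cell. Matrix genes were at -1.34 and chondro-osteogenic genes at -0.78, but Ibsp was seen in 67 of 308 knockout and 15 of 160 wild type cells and Col2a1 in 124 and 23. Uhrf1, a replication-linked epigenetic regulator, was 9.38-fold lower on 26 wild type UMIs, 57.7% of them in 1 cell. The cluster led by Fcrls and Cd72 held 106 wild type and 132 knockout cells. By the size rule 150 genes were higher and 138 lower among 9585.

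In whole-library sums of the tdTomato+ sort, contractile SMC genes were higher in knockout. Myh11, smooth muscle myosin heavy chain, was 9.51-fold higher (7.50 to 12.2), Cnn1, calponin, 9.27-fold (7.06 to 12.3), Myl9, a myosin light chain, 6.78-fold (5.72 to 8.07), Itga8, an integrin of SMCs, 7.55-fold (5.86 to 9.82) and Actg2 10.7-fold (6.23 to 19.7), with 42.9, 9.40, 44.2, 23.8 and 12.1 CPM in the heterozygous library. Of the contractile list 16 of 20 genes were at least 2-fold higher and 1 lower, at a median log2 ratio of 2.17. Tnnt2, a cardiac troponin (38.2-fold, 9.83 to 327), Sh3bgr (13.9-fold), Npy1r, a neuropeptide Y receptor (17.0-fold), and the chemokines Ccl12 (72.2-fold, 19.2 to 608) and Ccl4 (19.6-fold) were higher too, and Ccl2 was at 54.3, 54.5 and 171 CPM in wild type, heterozygous and knockout. The macrophage marker list was at 1.15 and MHC class II genes at 2.04 in the same pair, complement genes at 0.89 and TGF-beta and YAP targets at 0.71. Lower in knockout were Cxcl5 (45.1-fold, 15.3 to 220), the cartilage genes Cnmd, chondromodulin (28.5-fold), Col9a2, a collagen IX chain (11.4-fold), and Chad, chondroadherin (4.85-fold, 4.41 to 5.34), Chil1, a chitinase-like protein (4.79-fold), Stfa3 (6.02-fold), Prkg2 (at least 6.91-fold) and Wfdc21 (at least 5.81-fold). Their heterozygous levels were 10.6, 10.9, 8.52, 118, 530, 31.5, 5.38 and 3.04 CPM. Iigp1, an interferon-induced GTPase (13.2-fold), and Ifit3, an interferon-induced antiviral protein (7.80-fold), were lower, and 10 of 16 interferon response genes were at least 2-fold lower (median -1.37, 0 higher). Chondro-osteogenic genes were at -0.42 (percentile 0). Both libraries are those without usable cells. These log2 values are relative to total UMIs. By the size rule 508 of 8880 genes were higher and 188 lower, a higher share of 73.0%, and TMM scaling, which moved the ratios by 0.20 on the log2 scale, made this 297 and 300 (49.7%).

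The sorts were compared across genotypes to see what separates the GFP+ from the tdTomato+ sort, with edgeR's quasi-likelihood test on sums over the whole library and genotype as a block. Of 11359 genes 2 passed an adjusted p of 0.05. Gt(ROSA)26Sor, the transcript of the Rosa locus that carries the reporter, rose in GFP+ (log2 fold change 2.80, SE 0.31, adjusted p = 0.0379; 59.8, 69.6 and 57.4 CPM in wild type, heterozygous and knockout GFP+ against 6.97, 6.21 and 9.32 CPM in tdTomato+), in 3 of 3 pairs. Ifi27l2a, an interferon-induced gene, fell by 5.16 on the log2 scale (SE 0.49, adjusted p = 0.0195), with 0.41, 0 and 1.29 CPM in GFP+ and 21.2, 12.7 and 23.6 CPM in tdTomato+. Both were named after their values were seen, because no gene met the naming rule's level of 50 CPM. GFP is meant to mark earlier activity of Lgals3, not its current level. In the same test Lgals3 was lower in GFP+ in 3 of 3 pairs, at a log2 fold change of -1.47 (adjusted p = 0.408). Its levels were 202, 308 and 222 CPM in GFP+ against 629, 445 and 526 CPM in tdTomato+. Ccl2 had a log2 fold change of -1.05 (adjusted p = 0.808) and went in that direction in 1 of 3 pairs. It was at 55.8, 292 and 0.16 CPM in wild type, heterozygous and knockout GFP+. The tdTomato+ values were 54.5, 54.7 and 172 CPM. A sort effect that differs between genotypes counts as error in this test. At an unadjusted p of 0.05 there were 1365 genes, DESeq2 called 18 genes higher and 20 lower, no block left 1 higher and 0 lower, all libraries in the fit left 0 and 0, and leaving out the heterozygous pair left 682 higher and 910 lower from 4 libraries. Both tdTomato+ libraries of that last fit are those without usable cells. Adjusted over the list alone, 5 of 11 chemokines, 3 of 18 SMC modulation genes, 2 of 18 interferon response genes, 2 of 10 complement genes and 2 of 17 matrix proteases and inhibitors were lower in GFP+ and 2 of 18 chondro-osteogenic genes higher. Beside these, 2 of 7 macrophage markers were lower, and that list had a median log2 fold change of -2.04. Camera with its preset correlation called 12 of 19 lists, among them oxidative phosphorylation (lower, adjusted p = 8.9e-08), chemokines (lower, 0.000106), contractile (lower, 0.00213), matrix (higher, 0.00432) and chondro-osteogenic genes (higher, 0.0112). With an estimated correlation the adjusted p of these 5 lists was 0.604, 0.569, 0.604, 0.604 and 0.617, and no list was called. Of the 3 tdTomato+ libraries behind these values 2 stand apart in mitochondrial share (1.02% and 1.54%) and in Gm42418 and AY036118.

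Only the heterozygous genotype had cells in both sorts, 27 GFP+ and 640 tdTomato+ mesenchymal cells. There Gt(ROSA)26Sor was 11.8-fold higher in GFP+ (8.96 to 15.6), in 22 of 27 and 91 of 640 cells, and Plac9b, a gene with a near-identical copy, 10.3-fold higher (7.0 to 15). Exosc2 (6.99-fold), Col25a1 (8.65-fold), Zfp385c (16.8-fold), Olfr1369-ps1 (68.6-fold), Penk, the enkephalin precursor (14.2-fold), Otor (455-fold), Ccl7 (13.8-fold) and 1 of several genes that carry the symbol Ccl19 (19.6-fold) were higher with 52.8% to 99.1% of the GFP+ UMIs in 1 cell. Lower in GFP+ were Saa3 (39.7-fold, 19.2 to 98.8), Chad (27.5-fold, 11.8 to 84.8), Chil1 (8.24-fold, 6.72 to 10.2), Slurp1 (9.32-fold, 5.19 to 18.7) and Mmp13, a collagenase (5.07-fold, 4.37 to 5.91). Stfa3 (at least 16.0-fold), Dio2, a thyroid hormone deiodinase (at least 10.5-fold), Ltc4s, leukotriene C4 synthase (at least 8.98-fold), Col22a1 (at least 6.58-fold) and Cxcl5 (at least 5.72-fold) had 0 GFP+ UMIs. Of the GFP+ UMIs of Chil1, Slurp1 and Mmp13 (93, 11 and 177), 94.6%, 63.6% and 52.0% lay in 1 cell each. By the size rule 516 genes were higher and 631 lower among 11873. In mesenchymal cells of unsorted plaque Gt(ROSA)26Sor was at 21.9 CPM in wild type (19.4 to 24.6), 27.9 in heterozygous (25.5 to 30.4) and 52.1 in knockout (48.7 to 55.7), and in GFP+ mesenchymal cells at 62.3, 75.8 and 59.6 CPM.

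**Figure D4:**
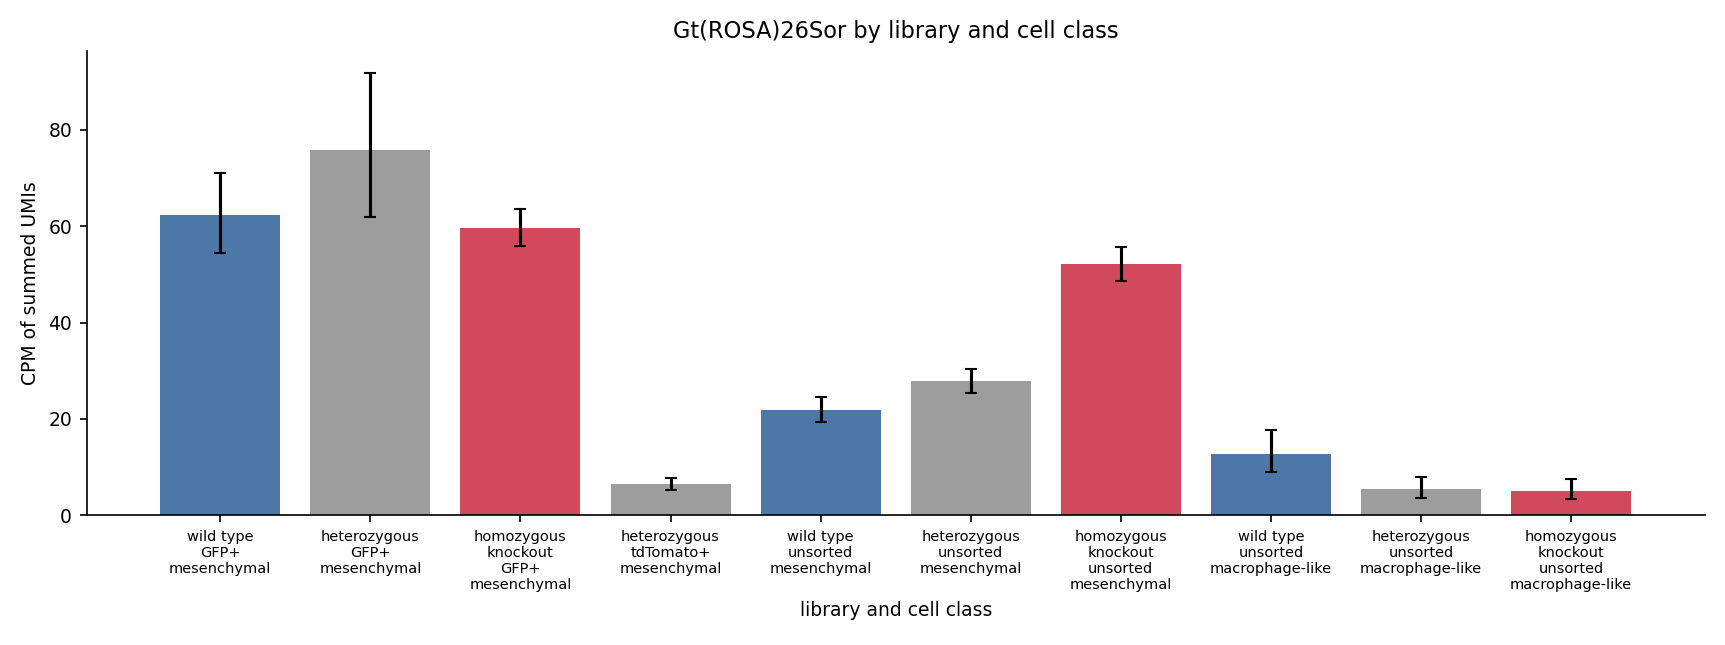
Gt(ROSA)26Sor in CPM, with exact 95% Poisson intervals for counting error, by library and cell class. GFP+ mesenchymal cells sit at 59.6 to 75.8 CPM and heterozygous tdTomato+ mesenchymal cells at 6.40 CPM.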

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

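The tests of free RNA for Ccl2, of all chemokines for Ccl7, of cluster mix for both chondro-osteogenic patterns, of free RNA for the unsorted one and of other splits of the libraries were chosen after the results were seen, as were the intervals over resampled cells; the other 5 tests here were chosen before.

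Several gene lists moved in opposite directions between knockout and wild type in 2 cell groups, a difference that was not tested, since each group has 1 library per genotype. Cytokine and NF-kB targets had a median log2 ratio of 0.37 in GFP+ mesenchymal cells and -0.47 in unsorted mesenchymal cells (difference 0.84), and 0.33 in macrophage-like cells, which put unsorted mesenchymal cells lower by a difference of -0.795. Between unsorted mesenchymal and macrophage-like cells the difference was 1.11 for chondro-osteogenic genes (0.32 and -0.78). In macrophage-like cells 47.3% to 53.8% of the wild type UMIs of Ibsp, Sox9, Hapln1 and Fmod lay in 1 cell each. The list was not compared there without such cells. The difference was -0.78 for resident-like macrophage genes (-0.32 and 0.46) and 0.471 for immediate early genes (0.26 and -0.21). GFP+ mesenchymal cells and tdTomato+ whole libraries differed by -2.43 for contractile genes (-0.26, which turned to 0.092 without each gene's top cell, and 2.17), -0.537 for matrix genes (-0.23 and 0.31), 0.736 for chondro-osteogenic genes (0.32 and -0.42), -1.63 for complement genes (-0.74 and 0.89) and -0.621 for hypoxia genes (-0.24 and 0.38). In the tdTomato+ pair neither library held usable cells. Xist, which no comparison used, stood at 989 CPM in the heterozygous unsorted library, with Ddx3y, a Y-linked gene, at 35.7 CPM there and 135 CPM in wild type.

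Ccl2 UMIs remained in unsorted knockout mesenchymal cells (228 UMIs, 13.8 CPM), although the GFP+ sort held 1. RNA set free by other cells was argued against: Ccl2 stood at 4.15% (1.58% to 7.98% over resampled cells) of its level in macrophage-like and monocyte-like cells, 22.7 times the median of 0.183% over 11 macrophage genes and above the highest of them (1.42%); a first rule in the code, 3 times that highest gene, was stricter than the written prediction and left this undecided. Doublets with macrophage-like or monocyte-like cells were argued against too. Only 1 of 892 mesenchymal cells had at least 10% of the macrophage-like median share of macrophage transcripts, and 0% of the 228 Ccl2 UMIs lay there. The upper bound of 1.60% takes UMIs as independent, although they lie in 41 cells. Cells that never recombined may hold the transcript: Gt(ROSA)26Sor, which was high in the GFP+ sort, was at 29.1 CPM in the 41 Ccl2-positive and 53.3 CPM in the other 851 cells, a ratio of 0.545 (0.347 to 0.817). That interval spans the 0.5 set beforehand and the 41 cells held 24 such UMIs, so this explanation stays open. The same ratio was 0.853 (0.618 to 1.16) in wild type and 0.823 (0.639 to 1.05) in heterozygous unsorted mesenchymal cells.

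Higher Ccl7 in knockout GFP+ mesenchymal cells was weighed against 3 explanations. With wild type clusters weighted to the knockout mix the ratio was 5.42 (2.35 to 29.4 over resampled cells), above the bound of 2. It rests on few wild type cells, however: 9 held Ccl7 and the smallest cluster has 2 cells. The cluster led by Nos2 and Il6 has 4 wild type against 103 knockout cells. Resampling cannot make up for so few cells, so the mix is not excluded. A few cells stay open: without the 5% of cells with the most Ccl7 UMIs the ratio was 6.83 (0.863 to 125 over resampled cells), but this takes 5 of 9 positive wild type and 27 of 106 positive knockout cells and leaves 7 and 214 UMIs. A rise of the whole chemokine list was argued against by its median of -0.44. That list holds Ccl2 itself, and a rise of only some chemokines was not tested. In the same cells cytokine and NF-kB targets were at 0.37 and immediate early genes at 0.66. A hypothesis left open is that the deletion next to it, or the loss of Ccl2, may raise Ccl7 in cells that recombined (ratio 5.42 at equal mix); no test here decided it, replicate animals and Ccl7 counted per allele would, and the higher Ccl7 of the knockout tdTomato+ library (1.91) does not weigh on it, since Ccl2 (3.15), Ccl12 (72.2) and the macrophage list (1.15 on the log2 scale) were higher there too.

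Chondro-osteogenic genes were higher in knockout mesenchymal cells of both the GFP+ and the unsorted library. Free cartilage RNA was argued against in the unsorted library, where the median was still 0.322 (0.123 to 0.660; random lists up to 0.065) after the mean UMIs of a knockout macrophage-like cell were taken off every knockout mesenchymal cell. A different mix of mesenchymal states, in clusters drawn without these genes, is consistent with the unsorted pattern: at equal mix the median was 0.068, inside the range of random lists (-0.07 to 0.10). In GFP+ the same weighting gave -0.12 (random lists -0.07 to 0.20), but it rests on wild type clusters of as few as 1 cell and leaves out 36 knockout cells, so the mix and a change within cells cannot be told apart there, nor can a few cells be excluded: without the 5% of cells with the highest share of these genes the median was 0.317 (0.127 to 0.891 over resampled cells, random lists up to 0.129). First versions of 2 tests were void, that of mix because its clusters rest on the list itself and that of free RNA, the -0.78 in macrophage-like cells, because 47.3% to 53.8% of the wild type UMIs of Ibsp, Sox9, Hapln1 and Fmod lay in 1 cell each while more knockout cells held Ibsp (67 of 308 against 15 of 160).

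Between the sorts 2 genes were called by edgeR. Of the 10 splits of the 6 libraries into 3 and 3, 2 called at least as many, the sort itself and 1 other. Both are among the 4 splits that set 1 library of each genotype on each side, while the other 6 called 0 or 1. The design has too few splits to give a share under 0.05. The highest other split called 34. That split set the wild type tdTomato+, knockout tdTomato+ and heterozygous GFP+ libraries against the rest, which points to a structure of the libraries apart from the sort. The first 2 of these are the libraries without usable cells. All 3 had the lowest total UMIs of the 6 libraries, at 3882762, 1829511 and 1516281 against 4953053 to 22664524 in the others. This split therefore also separates the libraries by depth.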

How the results depend on the processing

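Leaving out each gene's top cell, clustering with the genes otherwise left out, the heterozygous pair alone and sums over whole libraries were settings added after the data had been seen; the other settings were chosen before. Of 264 alternative values 168 stayed within tolerance. This was the interval of a value, 1.5 times a count or, for a gene list, a range around its median as wide as that of the random lists. The settings include removal of the 23 cells that Scrublet marked, although Scrublet was judged not to have worked here. The knockout over wild type ratio of Ccl2 in unsorted mesenchymal cells ran from 0.126 to 0.230, with 4 of 7 settings inside its interval, and Ccl2 in knockout GFP+ mesenchymal cells stayed between 0.0571 and 0.338 CPM. The cause of the changes below was not tested, except that a higher or lower UMI minimum tests fewer or more genes and thinning leaves fewer UMIs.

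Counts of genes at least 2-fold higher and lower are given in the order GFP+ mesenchymal, unsorted mesenchymal, macrophage-like, tdTomato+. With at least 100 UMIs they were 165 and 115, 97 and 92, 47 and 37, and 120 and 42; with at least 10, 826 and 572, 534 and 431, 406 and 334, and 1019 and 537. TMM scaling gave 297 and 300 for tdTomato+. Thinning gave 143 lower in GFP+, 138 higher and 78 lower in unsorted mesenchymal and 47 lower in macrophage-like cells. Without the cell with the most UMIs of each gene 609 were higher and 159 lower in GFP+, 90 were lower in macrophage-like cells, and the contractile list in GFP+ turned from -0.26 to 0.092; this setting takes a larger part of the 92 wild type cells than of the 535 knockout cells. All kept cells gave 331 lower in place of unsorted mesenchymal cells and 260 higher and 331 lower in place of macrophage-like cells. At most 5% mitochondrial UMIs gave 191 lower in GFP+. Another 6 list medians moved and 29 did not. Without each gene's top cell the chondro-osteogenic and cytokine lists in GFP+ rose to 0.502 and 0.691, and chemokines in unsorted mesenchymal cells went to -0.633 and interferon genes in macrophage-like cells to -0.200. With at least 100 UMIs chemokines and cytokines in unsorted mesenchymal cells were at -0.474 and -0.248.

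Thinned shares of mesenchymal cells with Ccl2 were 3.30% in wild type GFP+ and 6.81%, 4.10% and 1.35% in wild type, heterozygous and knockout unsorted cells. Ccl2 in mesenchymal cells at 5% mitochondrial UMIs was 66.5 CPM in wild type GFP+, 244 in wild type and 40.4 in knockout unsorted cells (ratio 0.166). At 20% the knockout had 24.0 CPM (ratio 0.230), and at 200 genes 16.3 CPM (ratio 0.149).

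At 5% mitochondrial UMIs wild type, heterozygous and knockout unsorted plaque had 39.6%, 54.8% and 43.9% mesenchymal and 44.9%, 35.1% and 46.2% macrophage-like; mesenchymal shares were then 71.9% in wild type GFP+, 88.0% in knockout GFP+ and 71.1% in heterozygous tdTomato+. At 20% mesenchymal cells made up 56.5% and 52.0% of wild type and heterozygous plaque and 79.6%, 77.1% and 83.4% of wild type GFP+, heterozygous GFP+ and heterozygous tdTomato+. At 200 genes macrophage-like cells were 20.7%, 23.6% and 25.2%, and mesenchymal cells 63.4% of knockout plaque, 67.6% of heterozygous GFP+ and 84.5% of heterozygous tdTomato+. At 1000 genes wild type plaque had 64.7% mesenchymal and 19.7% macrophage-like cells and knockout plaque 24.3% macrophage-like, with 99.1%, 100% and 99.5% mesenchymal in knockout GFP+, heterozygous GFP+ and heterozygous tdTomato+. Clustering with sex genes, haemoglobins, mitochondrial genes and Ccl2 gave 21.0%, 24.6% and 25.3% macrophage-like cells and 99.1%, 100% and 99.6% mesenchymal in the same 3 sorts.

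Between the sorts (1 gene higher and 1 lower with edgeR) no filter gave 73 and 103, no block 0 lower, all libraries in the fit 0 and 0 (2301 at an unadjusted p of 0.05), DESeq2 18 and 20, and the heterozygous pair alone by the size rule 516 and 631. Leaving out 1 genotype pair gave 4 to 682 higher and 20 to 910 lower, the most without the heterozygous pair. In that fit both remaining tdTomato+ libraries are those without usable cells, so its calls also separate cells from barcodes without cells. Camera with an estimated correlation called 0 of the 12 lists. Not run for the tdTomato+ genotype pair and the sorts were the cell filters, thinning and all kept cells, because 2 of the 3 tdTomato+ libraries have no usable cells.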

Other observations

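The test of a library-wide difference in Gt(ROSA)26Sor was chosen after its result was seen, and the test of its spread over cells before.

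Zbtb16, Fkbp5 and Tsc22d3 were higher in knockout mesenchymal cells of both libraries. In unsorted mesenchymal cells Zbtb16 was at a ratio of 9.41 (7.19 to 12.5), Fkbp5, an immunophilin of steroid receptor complexes, at 4.18 (3.64 to 4.82) and Tsc22d3, the glucocorticoid-induced leucine zipper, at 2.54 (2.29 to 2.82). GFP+ mesenchymal cells had ratios of 3.47 (2.26 to 5.62), 2.26 (1.79 to 2.88) and 2.15 (1.82 to 2.56). In macrophage-like cells Fkbp5 was at 3.01 (2.07 to 4.50), Tsc22d3 at 1.51 (1.25 to 1.82) and Zbtb16 at 1.15 (0.600 to 2.28). Fkbp5 and Tsc22d3 were chosen after their values were seen, and the 3 genes were not tested as a set.

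Gt(ROSA)26Sor in unsorted mesenchymal cells was 2.38-fold higher in knockout than in wild type (2.08 to 2.73), and higher in 9 of the 10 clusters compared. A hypothesis is that knockout plaque may hold a larger share of GFP+ cells. A mix of GFP+ and other cells should vary more than a sort, and the overdispersion of Gt(ROSA)26Sor UMIs was 1.86 in wild type unsorted against 0.434 in knockout GFP+ cells, a difference of 1.43 that passes the bound of 0.5 set beforehand. The heterozygous tdTomato+ sort, however, had 1.38 itself, so a high value does not single out a mix with GFP+ cells. The test also left out the knockout unsorted cells that the hypothesis concerns. Their overdispersion was 0.769, against 1.86 and 1.61 in wild type and heterozygous unsorted cells. The test therefore cannot give the share of GFP+ cells in knockout plaque, and the question stays open. A difference between the libraries in all cells was argued against by macrophage-like cells, where the ratio was 0.396 (0.227 to 0.681).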
